A study of Zea mays with 12 samples.

How the data were processed

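RNA from 24 samples of maize plants was compared on 12 two-colour Agilent oligonucleotide arrays, 2 samples to an array. The samples fall into 6 groups of 4: non-transgenic B73 plants and plants carrying an RNAi construct against chc101 or mbd101, each without (control) and with UV-B exposure. Each group has 2 Cy3 and 2 Cy5 samples, arranged as a double loop, and the series' design text calls the 4 samples of a group biological replicates. The sources do not settle what the non-transgenic plants are: the series title names siblings of the transgenic plants, the sample labels name B73, and the scanner files write NT. They are called B73 here, and whether a line and B73 differ only by the construct is therefore not known. The groups and dyes named in the scanner files match those of the channel labels on all 12 arrays. The sample titles, which name no dye, mostly give the Cy3 group first. On some arrays, such as that of B73 control with B73 UV-B, they give it last. The arrays sit on 3 slides of 4, and slides and scan days coincide. All 4 samples of mbd101 UV-B lie on slide 1, 3 of chc101 UV-B on slide 2 and 3 of B73 control on slide 3. Groups and slides are therefore in part confounded between samples, which bears on group means set against B73 control. Replicate numbers follow the order of deposition and pair nothing.

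The scanner files hold raw mean and local background intensity per spot and dye, made with Agilent Feature Extraction 9.5.3.1 per the file headers. They also hold processed signal intensity and a log10 ratio of Cy5 over Cy3, which the software had background-subtracted and dye-normalised per the file headers. The series' value table, deposited by the authors, holds a log2 ratio per spot. Set against the scanner files, it is on the scale of the log2 of Cy3 over Cy5 of the software's processed signals, with r between -1.00 and -0.97 against the software's ratio and medians per array between -0.25 and 0.13; whether it was centred further is not stated. The submitters' processing notes name Agilent Feature Extraction.

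Each array has 43451 spots, of which 1417 are controls and 42034 are probes, each spotted once. Mean signals were corrected for local background with normexp (offset 50) and log ratios were normalised within each array by loess, with controls and outlier spots at weight 0, in limma 3.58.1 (R 4.3.3). Control spots were left out, as were 456 spots marked as outliers among the probes tested. A probe was tested if well above background in at least 3 of the 4 samples of at least 1 group, which kept 37206 probes. All 12 arrays entered 1 linear model with the groups and a dye term, leaving 6 residual degrees of freedom, followed by empirical Bayes moderation. The 9 comparisons were tested at a Benjamini-Hochberg adjusted p of 0.05. Intervals of a change cover 95%. Levels per sample are log2 intensities after loess and quantile normalisation of the mean intensity between arrays.

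Percentages of spots well above background per channel ran from 65.1 to 90.7, with a median of 84.5. The background SD that normexp estimated was 761 in Cy3 and 1016 in Cy5 on the array of chc101 UV-B with B73 UV-B and 672 and 275 on that of mbd101 UV-B with mbd101 control, against a median of 4.73 over all channels, and the cause was not tested. Spike-in controls gave slopes of observed on expected log ratios of 0.923 to 1.00. The number of arrays limits the precision. Simulated errors were drawn independently for each probe and array, with no likeness within slides. On simulated arrays with the design, missing spots and spread of the 37206 probes, the fit of the UV-B response of B73 recovered 44.8% of probes changed 1.5-fold, 69.2% of those changed 2-fold, 90.0% of those changed 4-fold and 95.6% of those changed 8-fold, with 10.8 unchanged probes called per run.

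All 42034 probes have the description "Unknown", and their identifiers are mostly consensus or EST accessions. Only 4 probes matched the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0. No probe could be tied to chc101 or mbd101, and none of the 21 gene lists fixed beforehand had a matching probe, so the levels of the targeted genes and the list tests are not reported here. The rule for named genes was to give, where no annotated probe passed in a comparison, the 3 annotated probes with the smallest p as values, 1 probe per name with the highest mean intensity. Which names count as annotated was decided by hand after the files had been seen: 9 genes or elements on 21 probes, 19 of them tested, with the locus-like ZMATP70 left out. They were treated as 2 sets, chromosome cohesion and meiosis (15 tested probes) and the MuDR transposon (4 probes), which were tested with fry and camera. The 2 sets were formed after the names in the files had been seen.

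Alternatives fixed before the data were examined were no background correction, the software's processed ratios, the series' value table, median centring, 2 other filters on dim probes, no dye term, a dye term per slide, array weights, a separate-channel analysis, stricter thresholds and leaving out each array. Others were added after seeing the data: the median local background of each array in place of each spot's own, leaving out 2 arrays with nearly coinciding samples, leaving out the 3 arrays with the fewest detected probes, and fits within slides. Overlaps of lists were set against 20 simulations without effects, taking in each direction the simulated probes of smallest p, as many as in the real list; matching the lengths was chosen after the overlaps had been seen. The similarity of samples was measured as Pearson's r, across probes, of each sample's deviation from the mean of its dye.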

Results

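Transcript levels were measured in maize plants in which RNAi targeted chc101, a component of chromatin-remodelling complexes, or mbd101, a methyl-CpG-binding-domain protein, and in non-transgenic B73 plants. Plants of each genotype were sampled with and without UV-B exposure, 4 RNA samples per group, on 12 arrays. The comparisons address the response of each genotype to UV-B, the difference of each RNAi line from B73 in either condition, and whether UV-B responses differ between the lines and B73. Median signal over background was 72 to 134 per array in Cy3 and 36.8 to 104 in Cy5. The array of chc101 control with chc101 UV-B, the only direct pair of these groups, was the dimmest, with 70.9% of spots well above background as the mean of both dyes.

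None of the 37206 probes passed the threshold in any of the 9 comparisons (limma, Benjamini-Hochberg adjusted p). Before adjustment, 304 to 3330 probes lay under a p of 0.05, against 1860 for independent errors with no effect. The software's own ratios gave 1 probe in chc101 against B73 in control plants and 0 elsewhere, and the separate-channel analysis gave 0 throughout. Array weights, which ran from 0.141 to 87.2 and came with 1 convergence warning, gave 5647 probes for the UV-B response of chc101, 4889 for the UV-B response of mbd101, 11450 for chc101 against B73, UV-B, and 0 elsewhere. The highest weight fell on the array of chc101 UV-B with B73 UV-B, whose normexp background SDs were 761 and 1016. A dye term per slide gave 0 in each comparison. Within slide 2 the UV-B response of chc101 and chc101 against B73 under UV-B could be fitted, and within slide 3 the UV-B response of B73 and both lines against B73 in control plants. These fits gave 0 probes, but they had no dye term and 1 residual degree of freedom, so that the count says little. Slide 1 left no residual degrees of freedom. Below, each named value is followed by its range with single arrays left out and then by its range over all other settings tried, the fits within slides included.

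**Figure D1:**
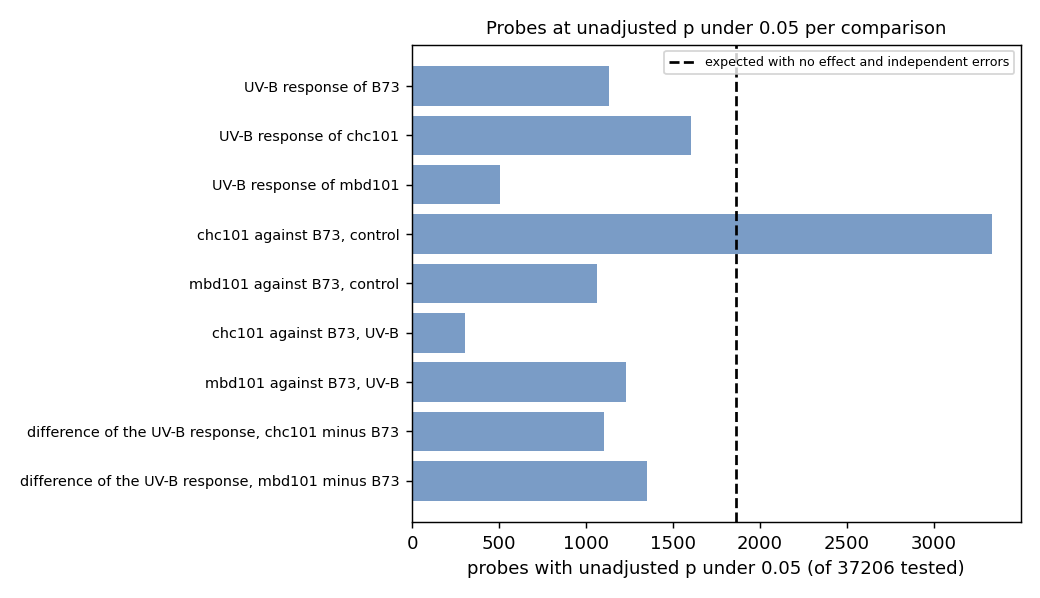
Bars give the number of the 37206 tested probes with an unadjusted p under 0.05 in each of the 9 comparisons, and the dashed line marks the 1860 that independent errors would give without any effect. Only chc101 against B73 in control plants, at 3330, lies above the line in the fit reported.

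Each of the 4 probes named for the MuDR transposon, the autonomous element of maize's Mutator family, was well above background in all 24 samples. The mudrA gene of MuDR encodes the transposase. The MuDRA probe had a log2 intensity of 8.67 ± 0.36 in B73 control, 8.44 ± 0.05 in B73 UV-B, 8.66 ± 0.09 in chc101 control, 8.80 ± 0.34 in chc101 UV-B, 8.73 ± 0.32 in mbd101 control and 8.78 ± 0.28 in mbd101 UV-B (SD, n = 4). The MuDRB probe ranged from 8.02 ± 0.35 in B73 control to 8.51 ± 0.07 in chc101 UV-B (SD, n = 4). Copies of MuDR-like sequence are numerous in maize, so the copies behind these signals cannot be told apart. Whether the autonomous element is among them is not known. The cohesion set holds ZmSMC1, ZmSMC3 and ZmRAD21, subunits of the cohesin ring that holds sister chromatids together, ZmSGO1, a shugoshin that protects cohesion at centromeres, and AM1, required for entry into meiosis. ZmSMC3 lay between 9.77 ± 0.12 in B73 control and 10.16 ± 0.33 in chc101 UV-B (SD, n = 4). Of 3 AM1 probes, 1 was well above background in all 24 samples and the others in at most 2 samples of a group. The differences given for each comparison come from the ratios within arrays, and intensities averaged per group can point the other way. This held for MuDR-TIRA in the UV-B response of B73, with a difference of 0.12 and group means of 7.84 ± 0.17 in control and 7.74 ± 0.16 under UV-B (SD, n = 4). Of the 27 values chosen by the rule for named genes over the 9 comparisons, 7 had group means pointing the other way, and of all 171 values of the tested named probes 58 did. The others of the 7 were MuDRA-21 in the UV-B response of chc101, ZmSGO1 in that of mbd101, AM1 in chc101 against B73 under UV-B, MuDR-TIRA and MuDRB in mbd101 against B73 under UV-B, and MuDR-TIRA in the difference of mbd101 from B73 in the UV-B response.

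**Figure D2:**
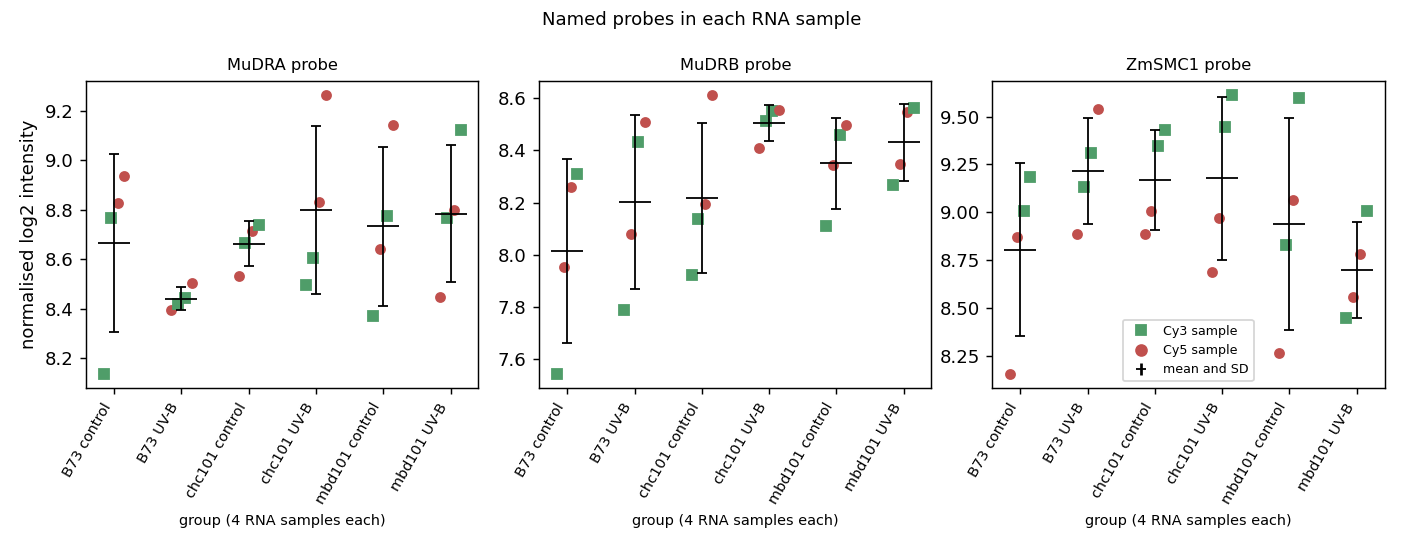
Normalised log2 intensity (vertical axis) of the MuDRA, MuDRB and ZmSMC1 probes in the 4 RNA samples of each group (horizontal axis). Squares are Cy3 samples and circles Cy5 samples, and bars give the mean and SD. The ranges of most groups overlap, while the 4 chc101 UV-B samples of MuDRB lie between 8.41 and 8.56 and the 4 B73 control samples between 7.54 and 8.31. These 2 groups are not set against each other in the 9 comparisons and were not tested. Of chc101 UV-B 3 samples lie on slide 2, and of B73 control 3 lie on slide 3.

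In B73, UV-B left no probe past the threshold, with 577 probes higher and 554 lower at an unadjusted p under 0.05. The cohesin subunit ZmSMC1 had a log2 difference of 0.22 ± 0.08, ZmSMC3 of 0.25 ± 0.16 and the MuDR-TIRA probe of 0.12 ± 0.08 (SE; adjusted p = 0.999 for each). Of the 15 cohesion probes 7 were above and 8 below 0, with 0 past the threshold over all probes and 0 when adjusted over the named probes alone. Of the 4 MuDR probes 3 were above 0 by the fitted differences, between -0.05 and 0.20, and 1 by the group means. ZmSMC1 ran from 0.16 to 0.32 without single arrays and from 0.10 to 0.39 in other settings, ZmSMC3 from 0.14 to 0.40 and from 0.12 to 0.31, and MuDR-TIRA from 0.02 to 0.20 and from 0.02 to 0.15. A dimmer ZmSMC1 probe was at 0.18 ± 0.13 (SE), and the other ZmSMC3 probes lay between -0.01 and 0.10. The unadjusted count of 1131 ran from 796 to 3893 without single arrays (probes at unadjusted p under 0.05: UV-B response of B73). It was highest without the array of B73 UV-B with chc101 control, and 2341 without that of chc101 control with B73 control. Other settings gave up to 2176 and, within slide 3 with 1 residual degree of freedom, 372.

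In chc101 plants, UV-B left no probe past the threshold, with 882 higher and 721 lower before adjustment. The 4 MuDR probes had fitted differences of log2 0.07 to 0.17, and none passed. The MuDR-TIRA probe had a difference of 0.17 ± 0.08, MuDRA of 0.15 ± 0.18 and MuDRA-21 of 0.07 ± 0.13 (SE; adjusted p rounding to 1 for each). MuDR-TIRA ran from 0.13 to 0.24 without single arrays and from 0.10 to 0.49 in other settings, MuDRA from -0.04 to 0.30 and from -0.12 to 0.36, and MuDRA-21 from 0.0050 to 0.17 and from -0.05 to 0.18. MuDRA turned negative without the array of chc101 control with chc101 UV-B, without the 3 arrays with the fewest detected probes and with median centring, and MuDRA-21 with median centring. Of the cohesion probes 11 of 15 lay above 0, between -0.05 and 0.09. Array weights let 5647 probes pass in the UV-B response of chc101, MuDR-TIRA at 0.19 (adjusted p = 0.0135) and MuDRA at 0.33 (adjusted p = 0.0289) among them, and 1 probe passed without the array of mbd101 control with chc101 control. The unadjusted count of 1603 became 2686 without the array of mbd101 UV-B with chc101 UV-B, 3614 without that of B73 UV-B with chc101 control and 1031 without that of chc101 control with chc101 UV-B, and other settings gave 895 to 11227.

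In mbd101 plants, UV-B again left no probe past the threshold, with 302 higher and 203 lower before adjustment. The only array that paired mbd101 UV-B with mbd101 control had normexp background SDs of 672 in Cy3 and 275 in Cy5. Counts without background correction and with the software's ratios, given below, were higher. Of single arrays left out, however, the highest count came without that of mbd101 UV-B with chc101 UV-B. Its normexp background SDs were 2.21 in Cy3 and 0.875 in Cy5. ZmSMC1 had a log2 difference of -0.18 ± 0.08, MuDRA-21 of -0.14 ± 0.13 and ZmSGO1 of -0.08 ± 0.08 (SE; adjusted p rounding to 1 for each). ZmSMC1 ran from -0.24 to -0.15 without single arrays and from -0.33 to -0.02 in other settings, MuDRA-21 from -0.19 to -0.05 and from -0.29 to -0.12, and ZmSGO1 from -0.17 to -0.02 and from -0.13 to 0.0020. The values nearest 0 of ZmSMC1 and ZmSGO1 came without background correction. A 2nd, dimmer ZmSMC1 probe had a difference of 0.04 ± 0.13 (SE). Array weights let 4889 probes pass in the UV-B response of mbd101, ZmSMC1 among them at -0.20 (adjusted p = 0.0205). The unadjusted count of 505 became 1155 without background correction and 1170 with the software's ratios, and all settings other than single arrays left out gave 357 to 9304. It became 328 without the array of mbd101 control with chc101 control, 1285 without that of mbd101 UV-B with mbd101 control and 1455 without that of mbd101 UV-B with chc101 UV-B. MuDR probes were 2 above and 2 below 0. Cohesion probes were 11 above and 4 below by the fitted differences, and 4 of 15 above by the group means. Since no probe passed in any UV-B response, none could be shared between 2 genotypes at the threshold. Before adjustment B73 and chc101 shared 47 higher and 44 lower probes, against 13.7 and 10.7 for independent lists and 66.3 and 53.2 in simulated arrays without effects, with lists of the same lengths. B73 and mbd101 shared 14 and 5, against 4.68 and 3.02 for independent lists and 32.8 and 25.9 simulated. For chc101 and mbd101 36 and 44 were shared, against 7.16 and 3.93 for independent lists and 39.9 and 28.3 simulated. In opposite directions lay 34, 38 and 26 probes of these 3 pairs, against 61.9, 29.3 and 34.5 simulated. The r across probes was 0.25 for B73 and chc101 against 0.10 simulated, -0.18 for B73 and mbd101 against 0.10, and 0.16 for chc101 and mbd101 against 0.10. The covariances were 0.0182 against 0.00740 simulated, -0.00939 against 0.00719 and 0.0105 against 0.00722. Simulated values here and below are means over 20 simulations with independent errors and no likeness within slides. How far the real arrays can stray from them without any effect is not known, so these gaps do not show an effect.

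The slope of each line's UV-B response on that of B73 could not be estimated in the fit reported. The variance of the B73 response across probes, 0.0575, was below its error variance of 0.0733.

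Between chc101 and B73 without UV-B, no probe passed, with 1803 higher and 1527 lower before adjustment. ZmSMC3 differed by 0.26 ± 0.16, MuDRB by 0.20 ± 0.13 and ZmSMC1 by 0.11 ± 0.08 (SE; adjusted p = 0.686, 0.714 and 0.747). ZmSMC3 ran from 0.12 without the array of mbd101 control with B73 control to 0.56 without that of chc101 control with B73 control, and from 0.10 to 0.37 in other settings. MuDRB ran from 0.09 to 0.27 without single arrays and from 0.05 to 0.30 in other settings, and ZmSMC1 from 0.08 to 0.17 and from 0.06 to 0.24. Dimmer ZmSMC3 probes lay between -0.04 and 0.04, and the other ZmSMC1 probe was at 0.20 ± 0.13 (SE). The unadjusted count of 3330 became 2051 with median centring and 1913 without the 3 arrays with the fewest detected probes. The 798 within slide 3 cannot be set against it, since that fit had no dye term and 1 residual degree of freedom. It was 2269 to 4263 without single arrays and at most 4593 in other settings. Of the MuDR probes 3 of 4 were above 0 and of the cohesion probes 7 of 15. The probe of TC300804, which the files pair with no gene name, had the smallest adjusted p, 0.240, at -1.32 ± 0.12 (SE), with group means of 7.37 ± 0.19 in chc101 and 7.89 ± 0.67 in B73 (SD, n = 4). It passed only without the array of mbd101 control with chc101 control, where the count was 2. TC310144 passed only with the software's ratios and with the deposited value table, which is on the same scale. Its samples spread from 6.60 to 11.69 within B73 control and from 9.56 to 11.64 within chc101 control.

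Between mbd101 and B73 without UV-B, no probe passed, with 643 higher and 419 lower before adjustment. ZmSMC1 differed by 0.24 ± 0.08, ZmRAD21 by -0.28 ± 0.19 and MuDRA-21 by 0.16 ± 0.13 (SE; adjusted p = 0.949 for each). ZmSMC1 ran from 0.19 to 0.29 without single arrays and from 0.17 to 0.67 in other settings, ZmRAD21 from -0.41 to 0.09 and from -0.75 to 0.06, and MuDRA-21 from 0.05 to 0.24 and from 0.01 to 0.30. ZmRAD21 turned positive without the array of mbd101 control with B73 control and without the 3 arrays with the fewest detected probes. Its dimmer probes, so close to background that they are a weak check, lay between -0.11 and 0.0077. The other ZmSMC1 probe was at 0.14 ± 0.13 (SE). MuDR probes were 3 above and 1 below 0. The unadjusted count of 1062 became 485 without the array of mbd101 control with chc101 control, 674 without that of mbd101 control with B73 control, 4215 without that of chc101 control with B73 control and 3223 with a dye term per slide, the highest of the other settings, which began at 611. Both comparisons use the same B73 samples. They shared 298 higher and 197 lower probes before adjustment, against 31.2 and 17.2 for independent lists and 272 and 183 in simulated arrays without effects, with lists of the same lengths, and 5 lay in opposite directions, against 12.7 simulated. Their covariance across probes was 0.0447, against 0.0363 simulated. Their r across probes was 0.50, against 0.50 simulated, and with each line set against its own 2 of the 4 B73 samples it lay between -0.21 and 0.04 over 6 such splits. In these splits the covariance lay between -0.0279 and 0.00515, and between -0.0665 and 0.00350 from the error of the fit alone. Probes are not independent replicates, and the simulations took errors as independent.

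Under UV-B, chc101 against B73 gave 128 higher and 176 lower probes before adjustment, and none passed. The only array that paired these 2 groups had normexp background SDs of 761 in Cy3 and 1016 in Cy5. It also had the smallest SD of log ratios, 0.255. Counts without background correction and with the software's ratios, given below, were higher. Of single arrays left out, however, the highest count came without that of B73 UV-B with chc101 control. Its normexp background SDs were 2.04 in Cy3 and 2.22 in Cy5. Whether the background of the paired array lowered the count cannot be told from these counts. ZmSMC1 differed by -0.14 ± 0.08, AM1 by 0.09 ± 0.07 and MuDRA-21 by 0.13 ± 0.13 (SE; adjusted p rounding to 1 for each). ZmSMC1 ran from -0.19 to 0.0033 without single arrays and from -0.31 to 0.07 in other settings, AM1 from 0.04 to 0.16 and from -0.0020 to 0.17, and MuDRA-21 from 0.03 to 0.23 and from 0.0046 to 0.22. ZmSMC1 turned positive without the array of chc101 UV-B with B73 UV-B, without the 3 arrays with the fewest detected probes and within slide 2, where AM1 turned negative. A dimmer ZmSMC1 probe had a difference of 0.07 ± 0.13 (SE) in the fit reported. With array weights 11450 probes passed, ZmSMC1 at -0.31 (adjusted p = 0.000578) and MuDRA-21 at 0.10 (adjusted p = 0.0474) among them. The unadjusted count of 304 ran from 144 without the array of B73 UV-B with mbd101 UV-B to 1011 without that of B73 UV-B with chc101 control, with 173, 629, 823 and 899 without those of chc101 UV-B with mbd101 control, chc101 control with chc101 UV-B, B73 control with B73 UV-B and mbd101 UV-B with chc101 UV-B. It was 860 without background correction, 1380 with the software's ratios and 1552 with the series' value table, and other settings gave 163 to 15537.

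Under UV-B, mbd101 against B73 gave 647 higher and 581 lower, and none passed. The 4 MuDR probes had fitted differences from -0.08 to -0.02, while the group means of all 4 were higher in mbd101, as for MuDRA with 8.78 ± 0.28 against 8.44 ± 0.05 in B73 (SD, n = 4), so that no direction can be given. ZmSMC1 differed by -0.16 ± 0.08, MuDR-TIRA by -0.07 ± 0.08 and MuDRB by -0.08 ± 0.13 (SE; adjusted p rounding to 1 for each). ZmSMC1 ran from -0.21 to -0.09 without single arrays and from -0.33 to -0.03 in other settings, MuDR-TIRA from -0.13 to -0.02 and from -0.17 to 0.02, and MuDRB from -0.21 to 0.04 and from -0.21 to 0.06. Both MuDR values turned positive in the separate-channel analysis, and MuDRB without the array of B73 UV-B with mbd101 UV-B. For the dimmer ZmSMC1 probe the difference was 0.0091 ± 0.13 (SE). At an unadjusted p under 0.05, the count of 1228 became 2879 without the array of mbd101 UV-B with chc101 UV-B and 2170 without that of B73 UV-B with chc101 control, and other settings gave 753 to 3810. Before adjustment both comparisons under UV-B shared 23 higher and 11 lower probes, against 2.23 and 2.75 for independent lists and 53.8 and 66.1 simulated with the shared B73 samples and lists of the same lengths, and 19 lay in opposite directions, against 2.25 simulated. Their r across probes was -0.02, against 0.50 simulated, and between -0.75 and -0.37 over the 6 splits of the B73 samples. In these splits the covariance lay between -0.137 and -0.0297, and between -0.0830 and 0.00359 from the error of the fit alone, so that a negative r can arise in part without any effect. In each of the 6 splits the covariance was more negative than that from the error, but the splits reuse the same samples. The simulations and the error of the fit also take arrays as independent, with no likeness within slides, so these gaps do not show an effect.

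The UV-B responses of the lines did not differ from that of B73 at the threshold for any probe. For chc101 minus B73, 510 probes were higher and 592 lower before adjustment, and ZmSMC1 had a difference of -0.25 ± 0.11, ZmSMC3 of -0.25 ± 0.21 and MuDRA of 0.20 ± 0.24 (SE; adjusted p rounding to 1 for each). ZmSMC1 ran from -0.35 to -0.12 without single arrays and from -0.44 to -0.05 in other settings, ZmSMC3 from -0.52 to -0.16 and from -0.48 to -0.09, and MuDRA from 0.03 to 0.35 and from -0.18 to 0.39. MuDRA turned negative with median centring and without the 3 arrays with the fewest detected probes. The other ZmSMC1 probe was at -0.14 ± 0.18 (SE), and dimmer ZmSMC3 probes lay between -0.08 and 0.06. In chc101 minus B73 the unadjusted count of 1102 became 660 without the array of chc101 UV-B with B73 UV-B and 1849 without that of chc101 control with B73 control, and other settings gave 740 to 4461.

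For mbd101 minus B73, the counts were 732 and 616. ZmSMC1 had a difference of -0.40 ± 0.11 (SE; adjusted p = 0.991), the smallest unadjusted p of the brightest named probes, and it did not pass when adjusted over the named probes alone, at 0.172. It ran from -0.49 to -0.35 without single arrays and from -0.54 to -0.20 in other settings, and the other ZmSMC1 probe was at -0.13 ± 0.18 (SE; adjusted p = 0.991). MuDRA-21 had a difference of -0.21 ± 0.17 and MuDR-TIRA of -0.14 ± 0.11 (SE; adjusted p = 0.991 for each). MuDRA-21 ran from -0.28 to 0.02 and from -0.33 to -0.06, and MuDR-TIRA from -0.20 to -0.04 and from -0.25 to 0.08. MuDRA-21 turned positive without the array of B73 control with B73 UV-B and MuDR-TIRA in the separate-channel analysis. Here the unadjusted count of 1348 became 2474 without the array of mbd101 UV-B with chc101 UV-B, 3093 without that of B73 UV-B with chc101 control, 828 without that of B73 control with B73 UV-B and 2580 without that of chc101 control with B73 control, and other settings gave 892 to 3769. Over all 18 tests of the MuDR and cohesion sets, the smallest adjusted p was 0.990 with fry, 0.922 with camera and 0.976 with an estimated correlation.

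RNA samples of 1 group did not have a higher mean correlation than samples of different groups. The mean r was -0.09 over 36 pairs of the same group on different arrays and -0.05 over 228 pairs of different groups (p = 0.854, one-sided permutation test with 100000 permutations of group labels within dyes). Grouping by treatment or by genotype gave p = 0.879 and 0.648 in the same permutation test. Samples on the same slide were more alike, with a mean r of 0.10 against -0.11 (p = 0.00042, permutation test of slides over arrays). The closest sample lay in the same group for 2 of 24 samples. The closest pair of all was 1 of chc101 control (replicate 2) and 1 of B73 UV-B (replicate 4), both Cy5 on slide 3, with r = 0.938.

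**Figure D3:**
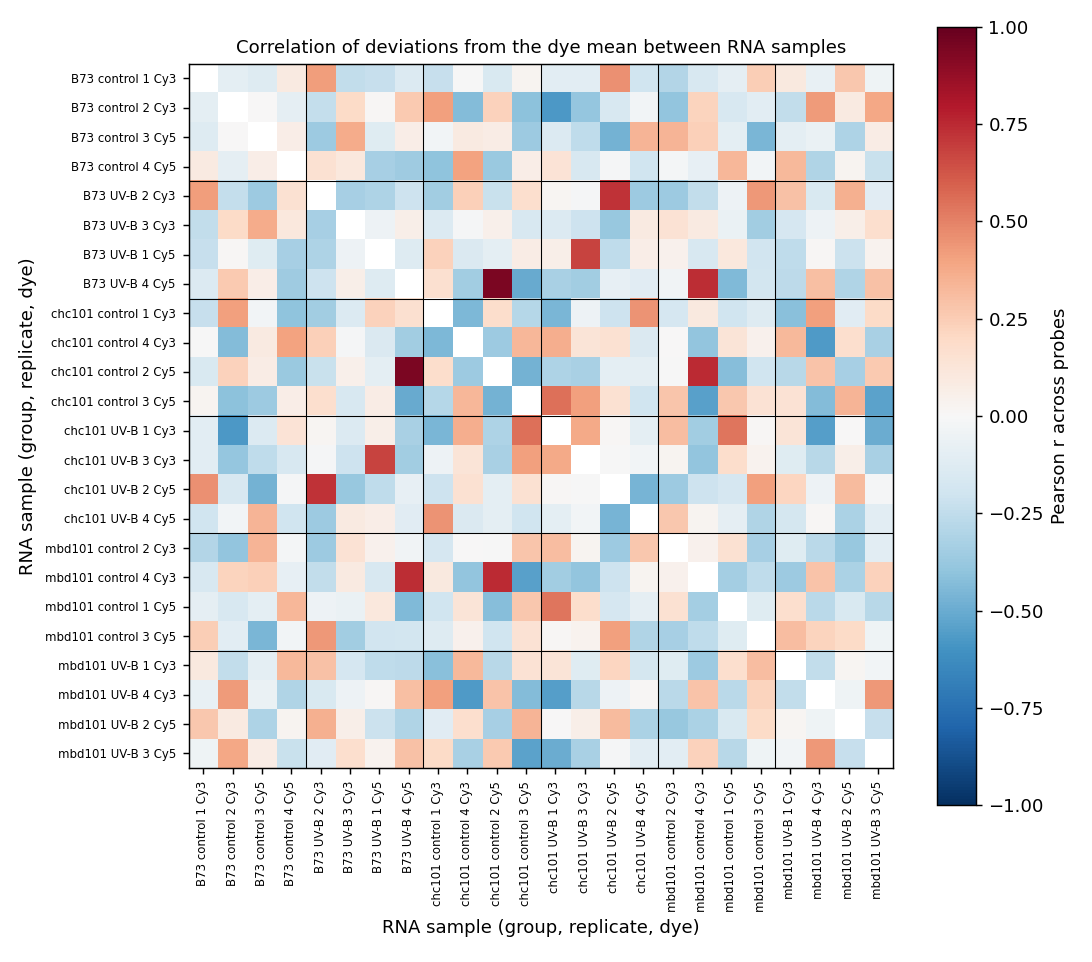
Pearson's r across probes between the deviations of all 24 RNA samples from the mean of their dye, ordered by group with lines between groups, pairs on the same array included and the diagonal left blank. The blocks of 1 group along the diagonal are not redder than the rest, and the darkest cell joins a chc101 control and a B73 UV-B sample.

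Within groups, single probes differed widely. Of 36772 probes without outlier spots, 266 spanned at least 16-fold, a size chosen after the values were seen, among the 4 samples of at least 1 group and 9 did so in all 6 groups. The most variable probe, TC305007, ranged from 7.11 to 12.71 in B73 control and from 6.83 to 13.67 in chc101 control. The 6 groups held a median of 19.9% of a probe's variance, and 67 of 100 random groupings held as much.

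**Figure D4:**
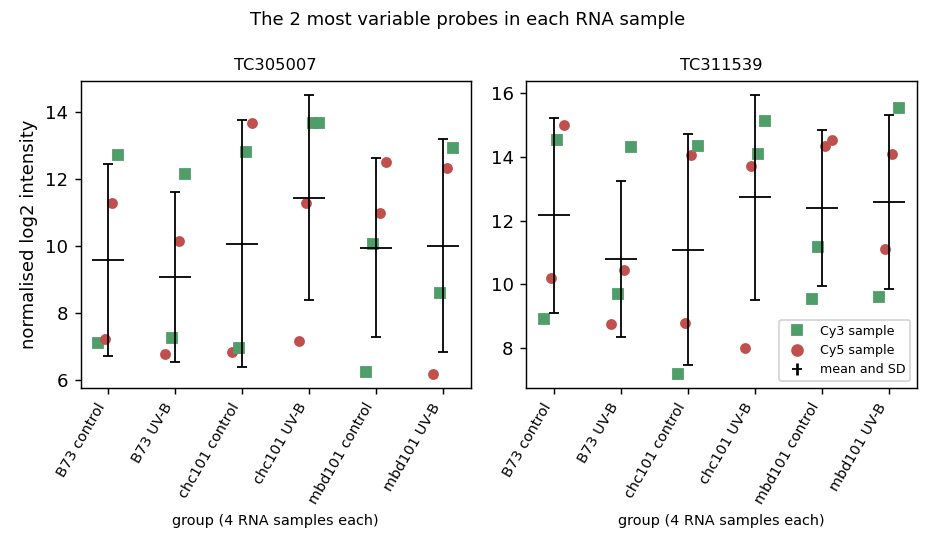
Normalised log2 intensity (vertical axis) of the 2 most variable probes in the 4 RNA samples of each group (horizontal axis), with mean and SD, squares for Cy3 and circles for Cy5. High and low samples of TC305007 and TC311539 occur in each of the 6 groups.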

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

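The probes examined here without a gene name were chosen after their values were seen. Of 90 groups of 4 samples, 4 held a sample far from the other 3 relative to the range of the group, and chance gives about 1 in 20. For BG836311 the gap took 0.964 of the range in B73 control, where replicate 3 lay at 10.11 and the others between 6.66 and 6.78. It took 0.864 of the range in B73 UV-B, where replicate 3 lay at 9.33, and 0.852 in chc101 UV-B, where replicate 4 lay at 9.62. For TC291769 it took 0.846 of the range in chc101 control, where replicate 3 lay at 7.45 and the others between 8.02 and 8.13.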

How the results depend on the processing

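Of 248 counts under 29 other settings, 241 were 0, as in the fit reported. The stricter thresholds were applied to that same fit, so their counts were 0 by construction. Those within slides had 1 residual degree of freedom and say little. The software's ratios and the series' value table each gave 1 probe for chc101 against B73 in control plants (TC310144; log2 7.72, against 3.87 in the fit reported), and the cause was not tested. Array weights gave 5647 probes for the UV-B response of chc101, 4889 for the UV-B response of mbd101 and 11450 for chc101 against B73, UV-B. Their estimation gave 1 convergence warning, and they ran from 0.141 to 87.2, the highest on the array of chc101 UV-B with B73 UV-B, which had the smallest SD of log ratios, 0.255. That array also had the highest normexp background SDs, 761 in Cy3 and 1016 in Cy5. The array of mbd101 control with chc101 control had a weight of 35.9, and no other exceeded 5.66. The probes that passed with array weights, named probes included, therefore rest mainly on few arrays. Leaving out each array gave 0 to 1 for the UV-B response of chc101, 0 to 2 for chc101 against B73 in control plants and 0 for the other 7; the non-zero values came without the array of mbd101 control with chc101 control. The settings added after seeing the data gave 0 in every comparison they could fit. At an unadjusted p under 0.05, 74 of 230 counts moved by over 1.5 times. Of 690 values of named probes, 18 had the opposite sign and 75 moved by at least 1 standard error; 5 passed the threshold, all with array weights. The slopes had no estimate in the fit reported. The B73 variance lay above its error variance in 3 settings, where the slopes of chc101 and mbd101 were 1.37 and 0.739 with array weights, 1.22 and -0.274 without the array of B73 UV-B with chc101 control, and -0.218 and -1.04 without that of chc101 control with B73 control. Camera and fry could not be run on the lists fixed beforehand. The dimmest array had a median signal over background of 36.8 in Cy5, the lowest of all channels, and how far this limits the results was not tested.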

Other observations

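The tests of the nearly coinciding pair and of the likeness of samples were chosen after the patterns had been seen, except those of the pair with the processed signals and without background correction. The splits of the samples were planned before their counts were seen. For weak arrays and for slides, counts of probes past the threshold were tried first, which were 0 both ways and decide nothing, and the likeness of samples was tested afterwards.

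Chance cannot be excluded for the unadjusted counts of any of the 9 comparisons. Past the threshold the real count is 0 in each, which all 35 splits of the 8 samples of a pair of groups and all 100 splits drawn for each difference of UV-B responses reach by construction, so these counts test nothing. The highest count of another split was 283 for the UV-B response of B73, 2 for that of chc101, 108 for that of mbd101, 2 and 199 for chc101 and mbd101 against B73 in control plants, 1 for each under UV-B, and 4 and 325 for the differences of chc101 and mbd101 from B73. The counts of 283, 108, 199 and 325 each came from a single split, with at most 10 probes in the others, and could reflect a structure of the samples other than the groups, but what arrays without such a structure give was not simulated. The splits include the real one, and they were not held to its balance of 2 Cy3 and 2 Cy5 samples per group. For example, 1 split of the B73 samples, with 4165 probes at an unadjusted p under 0.05, set all Cy3 against all Cy5 samples. At an unadjusted p under 0.05, 26, 15 and 32 of 35 splits gave as many probes as the UV-B responses of B73 (1131, highest other 7520), chc101 (1603, 4985) and mbd101 (505, 4044). For chc101 and mbd101 against B73 in control plants 7 and 23 did (3330, 5492 and 1062, 7719), and under UV-B 32 and 23 did (304, 5098 and 1228, 4155). For the differences, 59 of 100 did so in each line (1102, 4656 and 1348, 7042).

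The Cy5 samples labelled chc101 control (replicate 2) and B73 UV-B (replicate 4) nearly coincided: the SD of their log2 difference across probes, 0.109, ranked 1 from the smallest, against a median of 0.480 over all same-dye pairs on different arrays. An effect of slide and dye on all Cy5 samples of the slide is argued against by the other Cy5 samples there, whose r with either reached at most 0.0741. Liquid shared between the neighbouring arrays is argued against by their Cy3 samples, at r = 0.19, and normexp by r = 0.944 without background correction, while the software's processed signals, at 0.769, decide nothing. One RNA, or plants of one source, under 2 labels remains a candidate explanation, and which label would be wrong is not known. An effect of the slide on some of its samples stays open too: a Cy3 sample labelled mbd101 control (replicate 4), also on slide 3, correlated with both (r = 0.75 and 0.74), and B73 UV-B (replicate 2) and chc101 UV-B (replicate 2), on 2 arrays of slide 1, reached r = 0.72.

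That samples of a group were not found to be more alike than others may have several sources. Weak arrays stay open, since without the 3 with the fewest detected probes the one-sided permutation p for likeness within groups was 0.717, and so do slides, where samples resemble each other: among pairs on the same slide p was 0.986, and 0.944 without the 2 arrays of the closest pair. Reversed dye labels on some arrays stay open: turning the signs of arrays raised the variance explained by the groups from 45.6% to at most 58.9%, but 64 of 100 random assignments reached as much with the same freedom. Differences between the plants themselves, such as age or part sampled, were not tested, since the labels give neither. Simulations with the spread of these arrays were run for the UV-B response of B73 alone, where most 4-fold changes were recovered. They assumed independent errors, correct labels and no likeness within slides, so they do not show what these arrays could recover.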
